A study of Mus musculus with 3 samples.

How the data were processed

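Single-cell RNA sequencing (10x Chromium, Chip G, version 3.1 chemistry) was made from CD45-positive cells of mouse thalamus, isolated on ice with a tissue homogenizer and a 22% Percoll gradient and sorted by flow cytometry, per the labels' protocols. The deposited table holds raw UMI counts of 20586 genes in 7598 cells of 3 libraries, 1 per group. The submitters' processing notes name Cell Ranger 5.0, Seurat 4.0.1 and the genome build GRCm38, with no roles or order. The deposited count per cell equalled the sum of the table in 100% of cells. A second deposited table gives, per the file headers, the library, a sex call, a cluster number and a cell-cycle phase. It also gives the mitochondrial and ribosomal percent of each cell's UMIs. The deposited cells held 1301 to 5361 genes, 2100 to 19987 UMIs and under 5% mitochondrial UMIs, and the filter that left them is not given in the sources used here. No doublet caller was run here, and whether the authors removed doublets is not given in the sources used here. Cells that held both Xist and Y-linked UMIs were left out as an alternative.

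From the counts, the UMIs of all deposited cells of a library were summed per gene and divided by the library's total to give CPM. The design fixed before the data were examined compared microglia. The deposited clusters carry no cell type names. No cluster formed here had a microglial marker among its 10 leading genes, where naming took at least 3 markers of a class. The dendritic marker Ccr7 was among the leading genes of 1 cluster, and the choroid plexus marker Ttr among those of another. Since 99.9% of cells had at least 3 of the 8 microglial markers, all cells were summed instead. Leiden clustering (leidenalg 0.10.2 with python-igraph 0.11.9, resolution 0.5, 30 components of log-normalised counts of 2000 variable genes, 20 neighbours) and markers of 20 cell classes fixed before the data were examined served to name other cell types. No class named from the Leiden clusters had 50 cells in both libraries of a comparison, so none was compared gene by gene. Deposited cluster 3, with 67, 349 and 512 cells in WT IL-33, cKO IL-33 and WT vehicle, was not named and not compared, a choice made after the data were seen. Between libraries, only the deposited clusters that hold most cells were named, and their shares and defining genes were not compared.

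With 1 library per group no test was made and no p-value was computed. Each CPM has an exact Poisson interval, each ratio an exact conditional binomial (Clopper-Pearson) interval and each share an exact binomial (Clopper-Pearson) interval, all at 95% and all covering counting error only. For a share of 0 the limit set by a floor of 3 counts is given beside the exact bound. A library with 0 UMIs of a gene was set to a floor of 3 counts for a lower bound of the ratio. Log2 ratios used a pseudocount of 1 CPM. Genes at 50 CPM or more in either library were counted as at least 2-fold higher or lower. The genes named were the 15 with the highest and the 10 with the lowest log2 ratio among those whose interval excluded 1 and that were at least 2-fold apart, up to 4 members of each gene list with the largest ratio among members at 50 CPM or more, and Il1rl1 and Il33. A few genes that this rule names are not reported here. Genes singled out outside this rule, after the data were seen, were Il1rap, Mrc1, Tsc22d3 and the response genes with the highest ratios left in cKO IL-33. Gene lists were 19 sets fixed before the data were examined, and a list's median covers its members at 10 CPM or more in at least 1 library. Its interval came from 1000 Poisson redraws, its percentile from 10000 random lists of the same size drawn from 20 bins of mean expression, and members past 1.5-fold were counted.

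IL-33 response genes were chosen by the 2-fold rule on a random 50% of each library's cells and measured on the others. Shares of cells with an Il1rl1 UMI were also compared in cells thinned to 3000 UMIs. Thinning left out 353, 86 and 77 cells of WT IL-33, cKO IL-33 and WT vehicle. All other shares of cells are of unthinned cells, although depth differed between the libraries. The 4 Y-linked genes used were Ddx3y, Eif2s3y, Kdm5d and Uty. Gene positions are those of the GENCODE annotation of GRCm38, matched by symbol. The steps were tested on simulated sums, drawn as Poisson counts, in which 200 genes differed 3-fold. In the comparison of WT IL-33 with WT vehicle, 99.5% of them were past 2-fold, as were 0 of 3365 unchanged genes (3564 genes in all), and the intervals held the true ratio in 95.4% of genes. For cKO IL-33 against WT IL-33 these were 99.5%, 0 of 3426 and 95.7% (3625 genes), and for cKO IL-33 against WT vehicle 98.5%, 0 of 3254 and 96.2% (3451 genes). The intervals assume Poisson counts too, so the simulation checks the arithmetic and not whether that model holds. Neither covers the spread between cells, such as the 14 Ccl22 UMIs of WT vehicle that came from 2 cells.

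Alternatives fixed before the data were examined were TMM scaling (edgeR 4.0.16, used for these factors alone), totals without mitochondrial and ribosomal protein genes, cells weighted equally, cells without a UMI of any marker of T, B or NK cells, neutrophils or erythroid cells (which left out 1466 of 2202, 1851 of 2687 and 2061 of 2709 cells), thinned cells, a pseudocount of 10 CPM, no filter or 50 CPM for list members, 20 or 100 CPM for gene counts, 1.5-fold, 3-fold or 100 CPM for response genes, response genes chosen and measured on all cells, and Leiden resolutions of 0.3 and 1. Added after the data were seen were male-called cells, female-called cells without Y-linked UMIs, cells without Xist and Y-linked UMIs together, such cells with at most 5000 UMIs, and cells outside the border-associated macrophage-like cluster. The median log2 ratio of all genes compared lay within 0.05 of 0 under every scaling and cell set. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3.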

Results

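CD45-positive cells, a gate that takes microglia and other leukocytes, were sorted from mouse thalamus 4 hours after an injection into the cerebral ventricles and profiled by droplet single-cell RNA sequencing with unique molecular identifiers (UMIs). There were 3 libraries, 1 per group. The WT IL-33 library came from mice heterozygous for Cx3cr1-creER, an inducible recombinase driven by the fractalkine receptor gene of microglia and related macrophages, that received IL-33, a cytokine of the IL-1 family. The cKO IL-33 library came from mice that carried the same recombinase and homozygous floxed alleles of ST2, the IL-33 receptor chain encoded by Il1rl1, and that also received IL-33. The WT vehicle library came from recombinase heterozygotes given vehicle. No vehicle-injected library with the floxed alleles was analysed here, and the number of animals behind each library is not given in the sources used here. With 1 library per group, no difference has a replicate check and no test was made. All intervals are 95% intervals that cover counting error only, exact for counts, ratios and shares and from Poisson redraws for medians.

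The libraries held 2202 cells (WT IL-33), 2687 cells (cKO IL-33) and 2709 cells (WT vehicle), with 12127214, 17480958 and 18269042 UMIs in all. WT IL-33 cells were the shallowest, with a median of 3951 UMIs and 1832 genes per cell, against 5119 UMIs and 2186 genes in cKO IL-33 and 5544 UMIs and 2236 genes in WT vehicle. The median share of UMIs from mitochondrially encoded genes was 2.27%, 2.43% and 2.99%, and from ribosomal protein genes 10.6%, 12.8% and 15.02%, in the same order. Of the 7598 cells, 7593 (99.9%) had UMIs of at least 3 of 8 microglial markers such as Tmem119 and P2ry12. All deposited cells of a library were therefore summed, and values are given as CPM, the UMIs of a gene scaled to the total of that sum.

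Il1rl1 (chromosome 1, 40429570 to 40465415, plus strand, GRCm38), the gene targeted in the cKO, had 70 UMIs in WT IL-33, 224 in cKO IL-33 and 212 in WT vehicle. These are 5.77 CPM (4.50 to 7.29), 12.8 CPM (11.2 to 14.6) and 11.6 CPM (10.1 to 13.3). An Il1rl1 UMI was seen in 2.997% of WT IL-33 cells, 7.37% of cKO IL-33 cells and 6.83% of WT vehicle cells. With cells thinned to 3000 UMIs the shares were 25 of 1849 (1.35%), 98 of 2601 (3.77%) and 84 of 2632 (3.19%). The deleted exons are not given in the sources used here, and tags from the 3' end of the transcript can lie outside them, so these counts check nothing about the genotype label. No cell type that should lack Il1rl1 was present in numbers that would give its background. Il33 itself had 0, 0 and 3 UMIs in WT IL-33, cKO IL-33 and WT vehicle. Il1rap, the co-receptor chain that pairs with ST2, was at 17.6 CPM (15.3 to 20.1) in WT IL-33, 4.92 CPM (3.94 to 6.08) in cKO IL-33 and 5.25 CPM (4.26 to 6.42) in WT vehicle.

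Among the Leiden clusters formed here, the only one that could be named by the fixed markers, apart from cells with a microglial profile, was border-associated macrophage-like. It was led by Pf4, Cd163, Mrc1, F13a1 and Lyve1 and held 26 cells with a median of 14212.5 UMIs, in which all 8 microglial markers were also at 100 CPM or more. It made up 0 of 2202 WT IL-33 cells, which allows a share of up to 0.136% at the floor of 3 cells (exact upper bound 0.167%), 16 of 2687 cKO IL-33 cells (0.595%, 0.341 to 0.965%) and 10 of 2709 WT vehicle cells (0.369%, 0.177 to 0.678%). These shares hold for the cluster and do not show that WT IL-33 lacked such macrophages. WT IL-33 held 22 Pf4 UMIs in 7 cells and 12 Cd163 UMIs in 2 cells, with 0 UMIs of Lyve1. Deposited cluster 3 (928 cells) also had 5 of these markers among its 10 leading genes, but they came mostly from 25 of its cells that lay in the macrophage-like cluster. Pf4 was at 1313 CPM in those 25 cells and at 3.96 CPM in the other 903, so cluster 3 was left unnamed. P2ry12 was at 2391 CPM in the 25 cells and at 2808 CPM in the other 903, so it did not set them apart. Mrc1, a mannose receptor used as a marker of these macrophages, was at 7.59 CPM in WT IL-33, 49.4 CPM in cKO IL-33 and 53.4 CPM in WT vehicle. An Mrc1 UMI was seen in 448 of 2709 WT vehicle cells, far more than the 10 in the macrophage-like cluster. Its level in a library is therefore no measure of these macrophages.

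The libraries also differed in sex. By the deposited call, which was Female exactly where a cell had a UMI of Xist (the RNA that silences 1 X chromosome in female cells), WT IL-33 held 1107 female and 1095 male cells. The cKO IL-33 library held 2648 female and 39 male cells, and WT vehicle 8 female and 2701 male cells. The 39 male-called cKO IL-33 cells held neither Xist nor Y-linked UMIs. Of the 8 female-called WT vehicle cells, 7 also held Y-linked UMIs. These calls therefore do not show cells of the other sex in either library. Because the libraries differed in sex, the comparison of WT IL-33 with vehicle was repeated on male-called cells. That of cKO IL-33 with WT IL-33 was repeated on female-called cells without Y-linked UMIs. No sex-matched form exists for cKO IL-33 against WT vehicle.

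The effect of IL-33 in the control genotype was read from WT IL-33 against WT vehicle. Inflammatory cytokine and chemokine transcripts were among the 15 genes with the highest log2 ratios, ranked with a pseudocount of 1 CPM. Il12b, which encodes a subunit of the cytokine IL-12 (chromosome 11, 44400063 to 44414033), had 15083 UMIs against 2, or 1244 CPM against 0.109 CPM, an 11361-fold ratio (3144 to 93819). Il1b, encoding interleukin 1 beta (chromosome 2, 129364570 to 129371139), was at 1191 CPM against 0.657 CPM, 1813-fold higher (1038 to 3510). The chemokine genes Ccl4 (chromosome 11, 83662584 to 83664683), Ccl3 and Ccl22 were 341-fold (303 to 385), 209.5-fold (187 to 236) and 748-fold (446 to 1369) higher. P2ry12, a purinergic receptor gene of homeostatic microglia (chromosome 3, 59216272 to 59262871), was at 916 CPM against 3602 CPM, 3.93-fold lower (3.85 to 4.01).

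Others of those 15 genes covered receptors, enzymes and acute-phase products. Ch25h, cholesterol 25-hydroxylase, had 4096 UMIs against 3, a 2057-fold ratio (703 to 9978). Ccr7, a chemokine receptor of migrating dendritic cells, had 3316 UMIs against 0 and was at least 1665-fold higher. Marco, a scavenger receptor of macrophages, was at 313 CPM against 0.602 CPM, 520.4-fold higher (291 to 1043). Cd69, an activation marker of leukocytes, had 1539 UMIs against 3, a 773-fold ratio (264 to 3752). Saa3, an acute-phase serum amyloid gene, was 246-fold higher (147 to 451) and Hcar2, a receptor for hydroxybutyrate and niacin, 189-fold higher (133 to 279). Zfp811, a zinc-finger gene, had 1140 UMIs against 2, an 859-fold ratio (237 to 7099). In all, 515 of 4104 genes at 50 CPM or more in either library had a CPM at least 2-fold higher in WT IL-33 and 352 at least 2-fold lower, with 83 and 3 genes past 10-fold. Xist was also among the 15 genes, at 1024 CPM against 0.438 CPM. The vehicle library held 8 female-called cells, 7 of them with Y-linked UMIs.

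The lowest ratios after IL-33 were led by genes of dividing cells. Hist1h1b, a replication-dependent linker histone gene, was 26.2-fold lower (20.5 to 34.0), Cenpf, a kinetochore gene, 18.9-fold lower (13.6 to 27.0), and Mki67, the proliferation marker, 9.82-fold lower (8.26 to 11.8) at 11.4 CPM against 112 CPM. Hist1h1e, another linker histone gene, was 8.75-fold lower (7.84 to 9.78). Genes outside division were Cbfa2t3, a transcriptional co-repressor (12.5-fold lower, 9.95 to 16.0), the interferon-inducible Ifi27l2a (9.86-fold lower, 8.75 to 11.1) and the orphan receptor gene Gpr160 (9.78-fold lower, 7.87 to 12.3). Rnase6 was 8.87-fold lower, Plac8 8.58-fold lower and Rtn4rl1 8.15-fold lower.

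**Figure D1:**
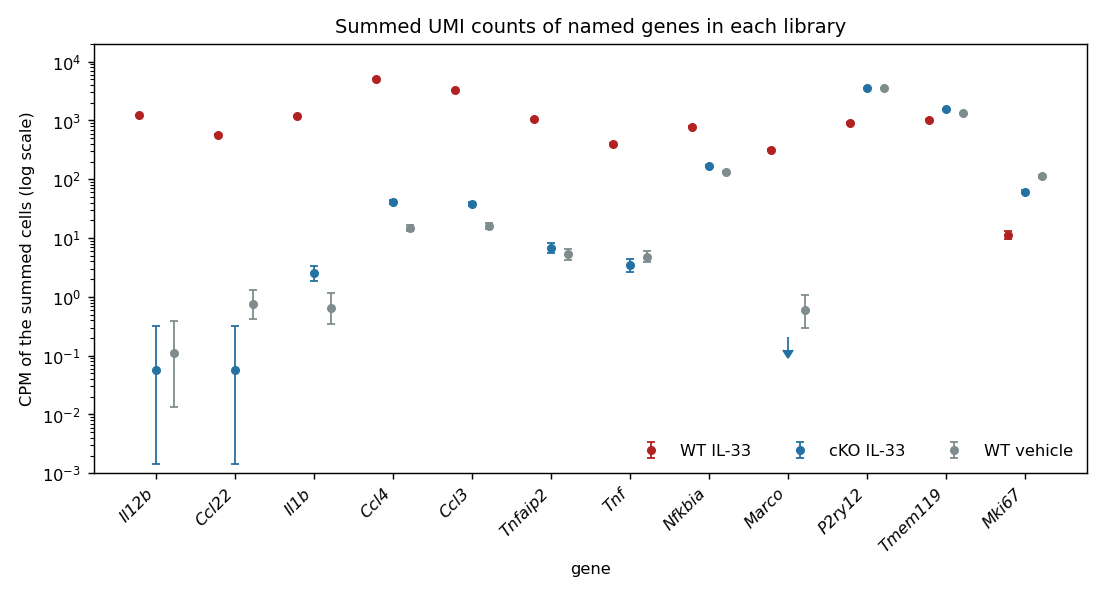
CPM on a log scale (y axis) of 12 genes (x axis) in the summed cells of WT IL-33 (red), cKO IL-33 (blue) and WT vehicle (grey). Points are values, bars exact 95% Poisson intervals covering counting error only, and the arrow the upper bound for Marco at 0 UMIs in cKO IL-33. Il12b was at 1244 CPM in WT IL-33 and under 1 CPM in the other libraries, and P2ry12 was at 916 CPM against 3527 CPM and 3602 CPM.

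Gene lists fixed beforehand showed which groups moved together in WT IL-33 against vehicle, each as the median log2 ratio of its measured members. All 23 NF-kB targets were at least 1.5-fold higher, with a median of 3.44 (3.32 to 3.58), above each of 10000 random lists matched on expression. Examples are Tnfaip2 (198-fold, 162 to 245), Nfkbiz (65.8-fold, 58.0 to 74.9) and Gadd45b (727-fold, 352 to 1810), with Bcl2a1d at 82.2-fold but uncertain, as near-identical paralogs can share its reads. Of 15 measured chemokines, 14 were higher, with a median of 4.70 (4.59 to 4.81), also above all 10000 random lists. Cxcl13, which attracts B cells, had 712 UMIs against 0 and was at least 358-fold higher. Of 13 cytokines and growth factors, 8 were higher and 1 lower (median 1.12, 0.99 to 1.26, but 0.29 with no CPM minimum and 4.67 for members at 50 CPM or more), among them Tnf at 400.4 CPM against 4.82 CPM (83.1-fold, 67.3 to 104) and Il1rn, the antagonist of the IL-1 receptor, with 803 UMIs against 2.

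Of 19 measured genes of pattern recognition, the receptors and adaptors that sense microbial and damage products, 12 were higher and 3 lower (median 1.34, 1.18 to 1.56). Tlr2 was 20.9-fold higher (19.5 to 22.3), Tlr1 12.96-fold (11.8 to 14.3) and Cd14, the lipopolysaccharide co-receptor, 9.83-fold (9.50 to 10.2) at 2111 CPM against 215 CPM. Among complement and phagocytosis genes 6 of 24 were higher and 7 lower (median -0.07). The anaphylatoxin receptor genes C3ar1 (11.9-fold, 11.4 to 12.4) and C5ar1 (11.01-fold, 9.97 to 12.2) were higher, while Gas6, a bridging ligand of phagocytic receptors, was 6.03-fold lower (5.43 to 6.71). Of 15 immediate early genes 10 were higher and 1 lower (median 0.98), with Dusp1 7.12-fold (5.95 to 8.57) and Ier2 3.87-fold (3.38 to 4.43) higher. Of 9 heat shock genes 6 were higher and 0 lower (median 1.02), such as the chaperone gene Hspa8 at 2.84-fold (2.76 to 2.91).

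Homeostatic microglial genes lay lower after IL-33, with 9 of 20 at least 1.5-fold lower, 0 higher and a median of -0.52 (-0.54 to -0.50), at the 1.52 percentile of random lists. Besides P2ry12, Gpr34 was 3.30-fold lower (3.20 to 3.41), Slc2a5, a fructose transporter gene, 2.93-fold (2.70 to 3.18) and Golm1 2.68-fold (2.58 to 2.78). Cell cycle genes had the lowest median, -2.44 (-2.57 to -2.20), with 15 of 17 lower and 0 higher, for example Top2a at 6.87-fold (5.82 to 8.15) and Stmn1 at 5.57-fold lower (4.99 to 6.23). The cell cycle median was -1.17 in cells with at most 5000 UMIs and without Xist and Y-linked UMIs together, and -1.15 with a pseudocount of 10 CPM. Deposited cluster 4, led by Hist1h1b, Mki67 and Top2a, had a median of 7305.5 UMIs. The cut at 5000 UMIs therefore leaves out many dividing cells and is no check of this median. Mitochondrially encoded genes had a median of -0.38, with 1 of 12 lower, mt-Nd5 (1.51-fold). This was at the 19.35 percentile of matched random lists, whose own median was -0.19, so it was within their range.

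The remaining lists had members on both sides after IL-33. Of 18 type I interferon genes, 4 were higher and 4 lower (median -0.03, but 0.32 in cells without other leukocyte markers, 0.079 in male-called cells and -0.21 for members at 50 CPM or more), with Isg15 2.96-fold higher and Ifi27l2a lower as above. MHC class II presentation had 3 of 6 higher and 2 lower (median 0.68, or 1.35 for members at 50 CPM or more), with the invariant chain gene Cd74 5.94-fold (5.59 to 6.32) and the costimulatory gene Cd80 4.91-fold higher, and H2-DMb1 3.68-fold lower. MHC class I presentation had 2 of 10 higher and 2 lower, with a median of 0.08 that was -0.0015 with totals free of mitochondrial and ribosomal genes and -0.0061 in male-called cells. Its members H2-K1 (3.76-fold higher) and H2-Q7 (4.42-fold higher) belong to a family with near-identical copies and are uncertain, and Psmb9, an immunoproteasome gene, was 2.30-fold lower. In the disease-associated microglia list 3 of 15 were higher and 4 lower (median -0.06), with Lpl, lipoprotein lipase, 12.5-fold higher and Apoe, apolipoprotein E, 2.27-fold lower. Glycolysis had 7 of 17 higher and 2 lower (median 0.23), led by the regulator Pfkfb3 (3.52-fold). The PI3K-Akt and mTOR list had 3 of 20 higher and 5 lower (median -0.12, or 0.15 for members at 50 CPM or more), with Pik3r5 8.71-fold higher, and the IL-33 receptor pathway 4 of 10 higher and 1 lower (median 0.27, or 0.94 for members at 50 CPM or more), with the kinase gene Irak2 3.29-fold higher. Extracellular proteases and cathepsins had 5 of 15 higher and 3 lower (median -0.07, or 0.092 with no CPM minimum), with Mmp14 5.29-fold higher.

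Sex and depth moved with the group in this comparison, and most WT IL-33 cells lay in deposited cluster 1 where most cells of the other libraries lay in clusters 0, 2 and 3. Between male-called cells of both libraries, 583 genes were at least 2-fold higher and 499 lower, and the medians were 3.53 for NF-kB targets, 4.88 for chemokines, -0.64 for homeostatic genes, 1.34 for pattern recognition and -2.36 for cell cycle genes. Among named genes, the log2 ratio in male-called cells was 7.43 against 6.75 over all cells for Saa3, -4.58 against -3.86 for Cenpf, -4.06 against -3.45 for Cbfa2t3 and -3.89 against -2.97 for Rtn4rl1. The 6 sex-linked genes had a median of -0.47 over all cells, or 2.67 for members at 50 CPM or more.

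The difference that went with the floxed ST2 alleles under IL-33 was read from cKO IL-33 against WT IL-33. The cytokine and chemokine transcripts that were high in WT IL-33 were far lower in cKO IL-33. Il12b had 1 UMI against 15083 and was 21742-fold lower (3902 to 858804), and Ccl22 had 1 UMI against 6952 and was 10021-fold lower (1798 to 395867). Il1b was 473-fold lower (352 to 651), Ccl4 123-fold lower (114 to 132) at 41.6 CPM against 5110 CPM, and Tnf 115-fold lower (89.2 to 150.3). P2ry12 was 3.85-fold higher (3.77 to 3.93) in cKO IL-33, at 3527 CPM.

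Further genes among the lowest log2 ratios in cKO IL-33, ranked in the same way, were Ch25h, with 0 UMIs against 4096 and at least 1968-fold lower, and Marco, with 0 against 3800 and at least 1826-fold lower. Ccr7 had 4 UMIs against 3316 (1195-fold lower, 466 to 4388), Saa3 was 254-fold lower (148 to 478), Gpr18, a lipid receptor gene, 164-fold lower (107 to 265), and Tnfaip2 153-fold lower (128 to 185). Genes with the highest ratios were again led by Hist1h1b, 11.8-fold higher (9.15 to 15.3). Cbfa2t3 was 8.22-fold (6.50 to 10.5), Gpr160 7.34-fold and Rtn4rl1 7.06-fold higher. Slc40a1, the iron exporter ferroportin, was 6.35-fold higher (5.55 to 7.29), Il7r, the interleukin 7 receptor, 6.14-fold (5.54 to 6.81), Mex3b, an RNA-binding protein gene, 6.31-fold and the ETS factor gene Etv1 5.73-fold. Pmepa1, a TGF-beta target that limits TGF-beta signalling, was at 862 CPM against 165 CPM, 5.22-fold higher (4.98 to 5.47). Mki67, Ifi27l2a and Tln2 were 5.43-fold, 5.09-fold and 5.08-fold higher, and the noncoding C030034L19Rik and Gm10790 6.53-fold and 5.15-fold. In all, 409 of 4151 genes were at least 2-fold higher in cKO IL-33 than in WT IL-33 and 465 at least 2-fold lower, with 1 and 77 past 10-fold.

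By list, all 23 NF-kB targets were at least 1.5-fold lower in cKO IL-33 than in WT IL-33, with a median of -3.36 (-3.51 to -3.25), and the costimulatory receptor gene Cd40 was 304-fold lower (130 to 939). Of 15 chemokines, 14 were lower, with a median of -4.93 (-5.02 to -4.79), or -4.75 with members at 0 set to their bound. Both medians lay below each of 10000 random lists. Pattern recognition had 11 of 19 lower and 4 higher (median -1.19), with Tlr2 21.7-fold and Cd14 7.34-fold lower. Cytokines and growth factors had 7 of 13 lower and 1 higher (median -0.84, but -0.22 with no CPM minimum and -4.60 for members at 50 CPM or more), heat shock 6 of 9 lower (median -1.31, or -0.68 with no CPM minimum), immediate early genes 7 of 15 lower and 3 higher (median -0.39, or -0.14 in female-called cells without Y-linked UMIs) and glycolysis 6 of 17 lower and 2 higher (median -0.35). Homeostatic genes had 13 of 20 higher and 0 lower (median 0.62, 0.61 to 0.64), with Gpr34 4.02-fold (3.89 to 4.15) and Slc2a5 3.45-fold higher. Cell cycle genes had 13 of 17 higher and 0 lower (median 1.60, 1.34 to 1.77), with Stmn1 3.37-fold higher. That median was 0.88 in cells with at most 5000 UMIs, a cut that leaves out many dividing cells, and 0.69 with a pseudocount of 10 CPM. The deposited S and G2M shares went the other way, being lower in cKO IL-33 than in WT IL-33. The PI3K-Akt and mTOR list had 7 of 20 higher and 2 lower (median 0.40), Inpp5d, the phosphatase SHIP, being 2.19-fold higher and Pik3r5 8.06-fold lower.

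Lists with members on both sides between cKO IL-33 and WT IL-33 were MHC class II presentation (2 of 6 higher, 3 lower, median -0.55, or 0.10 with no CPM minimum and -1.26 for members at 50 CPM or more, Cd74 6.90-fold lower), MHC class I presentation (1 of 10 higher, 2 lower, median -0.04, or 0.0050 with totals free of mitochondrial and ribosomal genes) and type I interferon genes (3 of 18 higher, 6 lower, median -0.10, or 0.12 for members at 50 CPM or more). Complement and phagocytosis had 6 of 24 higher and 6 lower (median 0.14), with C3ar1 10.5-fold lower and Gas6 4.35-fold higher. The disease-associated list had 5 of 15 higher and 2 lower (median 0.10), with Lpl 20.1-fold lower, and the proteases and cathepsins 4 of 15 higher and 5 lower (median 0.15). The IL-33 receptor pathway had 1 of 10 higher and 3 lower (median -0.12, or -0.81 for members at 50 CPM or more), and mitochondrially encoded genes 0 of 12 past 1.5-fold (median 0.16). The sex-linked genes had a median of -4.10. Between female-called cells without Y-linked UMIs, 318 genes were at least 2-fold higher in cKO IL-33 and 389 lower, with medians of -3.12 for NF-kB targets, -4.56 for chemokines, 0.54 for homeostatic genes and 1.38 for cell cycle genes. Among named genes, the log2 ratio in those cells was -9.22 against -10.20 over all cells for Il12b, -7.69 against -8.40 for Il1b, -7.63 against -8.40 for Ch25h, -7.13 against -7.80 for Ccr7, -6.10 against -6.91 for Ccl4 and -5.71 against -6.77 for Saa3.

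**Figure D2:**
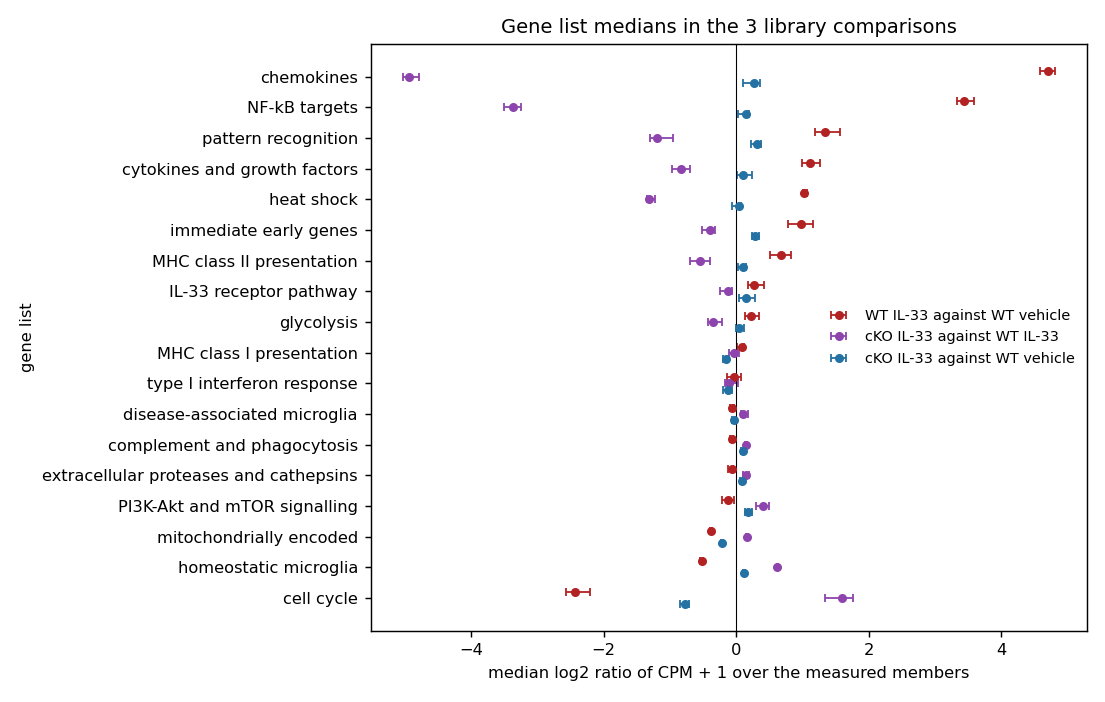
Median log2 ratio of CPM + 1 over the measured members of 18 gene lists (y axis) for WT IL-33 against WT vehicle (red), cKO IL-33 against WT IL-33 (purple) and cKO IL-33 against WT vehicle (blue), with 95% intervals from Poisson redraws that cover counting error only. Chemokines lay at 4.70, -4.93 and 0.27 and cell cycle genes at -2.44, 1.60 and -0.77.

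What remained of the IL-33 difference with the floxed alleles was read from cKO IL-33 against WT vehicle, in which genotype, injection and sex all differ. Of 3585 genes, 11 were at least 2-fold higher in cKO IL-33 and 4 lower, and 2 of each were sex-linked (Xist, Tsix, Ddx3y and Eif2s3y). The 9 other higher genes included Sult1a1, a sulfotransferase gene, at 3.37-fold (3.08 to 3.70), Fkbp5, a co-chaperone of the glucocorticoid receptor, at 2.89-fold (2.75 to 3.04) and Ddit4, a stress-induced inhibitor of mTOR, at 2.42-fold (2.28 to 2.56). Nfkbia, the NF-kB inhibitor and target gene, was at 169.8 CPM against 135 CPM, 1.26-fold higher (1.19 to 1.33), where WT IL-33 had 778 CPM. The split was 9 higher and 6 lower with TMM scaling, and 11 higher and 7 lower with totals free of mitochondrial and ribosomal genes.

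The other higher genes in cKO IL-33 against WT vehicle were C030034L19Rik (2.27-fold), the chromatin gene Jade2 (2.21-fold), the cation channel gene Trpm2 (2.19-fold), the cyclin gene Ccnd3 (2.15-fold, 2.03 to 2.28) and the cytokine receptor gene Lifr (2.06-fold, 1.93 to 2.20). Gm22146 (2.11-fold, chromosome 17, 28446861 to 28447148) lies within the span of Fkbp5 (28399094 to 28517527) and is uncertain for that overlap. Tsix, the antisense partner of Xist, is uncertain for the same reason. The other lower genes were the noncoding Gm26917 (2.47-fold, 2.34 to 2.61) and Hist1h1b (2.23-fold, 2.07 to 2.39). Xist was at 2742 CPM against 0.438 CPM (6263-fold, 3178 to 14506), Tsix was 770.1-fold higher (354 to 2099), and Ddx3y and Eif2s3y, with 0 UMIs in cKO IL-33, were at least 586-fold and 493-fold lower. Within the WT IL-33 library, all 9 of the higher genes that are not sex-linked had higher CPM in cells with Xist and no Y-linked UMI than in cells with Y-linked UMIs and no Xist, 8 of them by more than counting error. Those Xist cells also lay less often in deposited cluster 1 (74.2% against 87.2%), and the 9 genes were not compared within a cluster. Sex is therefore not separated there from the inflammatory state of the cells.

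Genes that differed after IL-33 in the control genotype were followed into cKO IL-33, with the genes chosen on 50% of each library's cells and measured on the others. The 520 genes chosen as at least 2-fold higher in WT IL-33 had a median log2 ratio of 1.58 against WT vehicle in WT IL-33 and 0.12 (0.10 to 0.14) in cKO IL-33. In cKO IL-33, 22 of the 520 (4.23%) were at least 1.5-fold higher than in vehicle, 10 at least 1.5-fold lower and 488 within 1.5-fold. The 362 genes chosen as lower had medians of -1.33 in WT IL-33 and 0.00 (-0.01 to 0.02) in cKO IL-33, with 10 of them at least 1.5-fold lower, 8 higher and 344 within 1.5-fold. Both comparisons use the same vehicle library. Beyond the sex-linked genes, some response genes kept a higher log2 ratio in cKO IL-33, ranked with a pseudocount of 1 CPM. Their values here cover all cells of each library, including those used for the choice. The highest were in order Vcam1, an adhesion molecule (120 UMIs against 20, 6.27-fold, 3.89 to 10.6), Gadd45b (71 against 7, 10.6-fold, 4.89 to 27.3), Rcan1, a calcineurin regulator (3.09-fold, 2.60 to 3.69), Ccl4 (728 UMIs against 274, 2.78-fold, 2.41 to 3.20) and Jdp2, an AP-1 family repressor (2.63-fold, 2.27 to 3.06). They were followed by Ccl3 at 2.37-fold (2.06 to 2.73), Il1b at 3.83-fold (1.99 to 7.97) and Socs3, a cytokine signalling inhibitor, at 2.11-fold (1.83 to 2.43). Of the cKO IL-33 UMIs, 35 of the 2687 cells, those in deposited cluster 1, held 392 of 728 for Ccl4, 171 of 654 for Ccl3 and 22 of 44 for Il1b. These genes are among the leading genes of cluster 1, so cells placed in it are rich in them by construction. The counts do not show a separate group of responding cells.

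**Figure D3:**
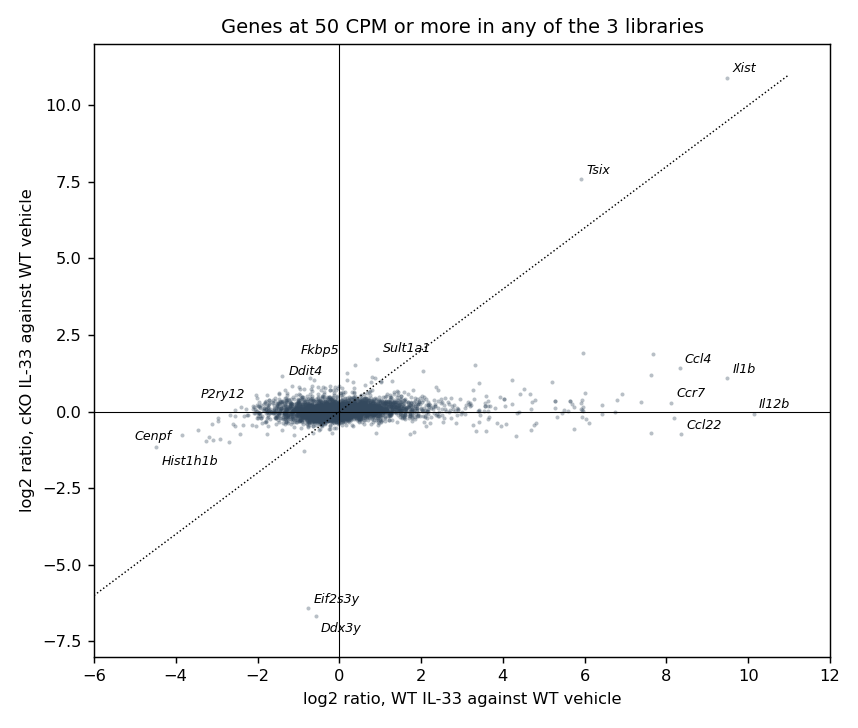
Log2 ratio of CPM + 1 against WT vehicle in WT IL-33 (x axis) and in cKO IL-33 (y axis) for genes at 50 CPM or more in any library, 1 point per gene, with lines at 0 and a dotted line of equal ratios. Most genes higher or lower in WT IL-33 lie near the horizontal line, while Xist and Tsix lie far above it and Ccl4 at 1.41 on the y axis, and the chosen higher genes had medians of 1.58 (x axis) and 0.12 (y axis).

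Of the 19 lists in cKO IL-33 against WT vehicle, 5 lay within the top 2.5% of random lists or above and 5 within the bottom 2.5% or below. Cell cycle genes had the lowest median apart from the sex-linked genes, with 15 of 17 at least 1.5-fold lower, 0 higher and a median of -0.77 (-0.85 to -0.71), below each of 10000 random lists. That median was -0.13 in cells with at most 5000 UMIs and without Xist and Y-linked UMIs together, a cut that leaves out many dividing cells. Top2a was 2.02-fold lower (1.85 to 2.21), Mki67 1.81-fold (1.68 to 1.95) and Hmgb2 1.71-fold (1.63 to 1.79). NF-kB targets had 3 of 23 higher and 0 lower (median 0.14, 0.03 to 0.20, at the 85.0 percentile), and chemokines 3 of 15 higher and 2 lower (median 0.27, or 0.15 with members at 0 set to their bound, 99.4 percentile of the first), with Ccl9 1.64-fold higher. Pattern recognition had 2 of 19 higher and 1 lower (median 0.31, 0.22 to 0.38, above each random list), with the RNA sensor gene Tlr7 1.68-fold higher (1.60 to 1.75). Immediate early genes had 3 of 15 higher and 0 lower (median 0.28, 99.9 percentile), and the IL-33 receptor pathway 2 of 10 higher (median 0.14). Homeostatic genes had 0 of 20 past 1.5-fold either way and a median of 0.12 (0.11 to 0.13, 99.7 percentile), with Selplg 1.39-fold higher.

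The other medians of cKO IL-33 against WT vehicle lay between -0.21 and 0.17, leaving out the sex-linked genes at -5.01 (0.58 for members at 50 CPM or more). They were 0.17 for the PI3K-Akt and mTOR list (1 of 20 higher, Ddit4, 99.4 percentile), 0.11 for cytokines and growth factors (1 of 13 higher), 0.10 for complement and phagocytosis (1 of 24 higher, 1 lower) and 0.10 for MHC class II presentation (0 of 6 past 1.5-fold, and -0.060 in cells with at most 5000 UMIs). They were 0.09 for proteases and cathepsins (0 of 15), 0.05 for glycolysis (1 of 17 higher, and -0.018 with TMM scaling), 0.04 for heat shock (0 of 9, and -0.025 with TMM scaling) and -0.03 for the disease-associated list (1 of 15 lower). Type I interferon genes had 2 of 18 lower (median -0.12, or 0.090 in cells without other leukocyte markers, 0.04 percentile), led by Ifi27l2a at 1.94-fold (1.84 to 2.04), MHC class I presentation 0 of 10 past 1.5-fold (median -0.16, 0.74 percentile) and mitochondrially encoded genes 0 of 12 (median -0.21, 2.12 percentile).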

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

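Chosen only after the result was seen were both tests of the cells with Xist and Y-linked UMIs, and the restrictions to male-called cells and to cells with at most 5000 UMIs.

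In WT IL-33, 305 of 2202 cells (13.9%, 12.4 to 15.4%) held UMIs of Xist and of Y-linked genes, a co-occurrence within cells that the comparisons do not use. It was seen in 0.112% of cKO IL-33 and 0.258% of WT vehicle cells. Those libraries were nearly all of a single sex by the deposited call (2648 of 2687 female, 2701 of 2709 male). Their low shares were therefore set by sex make-up and say nothing about how often cells were captured together. Captures of cells of the same sex go unseen in every library. Free RNA in the suspension would give Xist cells a like rate of Y-linked UMIs at every depth, but that rate was 13.7 times (8.06 to 25.2) as high in Xist cells above 10000 UMIs as in those at 4000 UMIs or fewer. Male and female cells captured together remain a candidate explanation: Xist per 10000 UMIs was 0.422 times (0.405 to 0.441) that of shallow Xist cells without Y-linked UMIs, and the median depth was 10780 UMIs against 3870.5 in all Xist cells without them. The share of Xist cells with Y-linked UMIs was 2.68% at 2000 to 4000 UMIs and 74.9% above 10000 UMIs. No biological explanation was tested.

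A second pattern weighed was the genes higher in WT IL-33 than in WT vehicle, whose median log2 ratio over all cells was 1.60 (513 genes outside the sex-linked list). A different sex make-up would need a median near 0 between male-called cells, where it was 1.69. Doublets would need it to vanish in cells with at most 5000 UMIs and without Xist and Y-linked UMIs together, where it was 1.63. Lower depth per cell was predicted to make it vanish at 3000 UMIs per cell, where it was 1.62. Random thinning keeps each gene's expected share of a cell's UMIs, and CPM is already scaled to the total. The value at 3000 UMIs therefore cannot decide whether depth plays a part. A difference between single preparations stays open and cannot be told apart from the injection, because there was 1 library per group. An effect of IL-33 through ST2 therefore remains a hypothesis.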

How the results depend on the processing

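The settings restricted by sex call, by Xist and Y-linked UMIs, to 5000 UMIs or to cells outside the macrophage-like cluster were chosen only after the data were seen, and the others were planned. Of 64 alternative gene counts, 53 stayed within 1.5 times the value reported. Of 665 alternative list medians 465 stayed within their counting interval, 191 moved outside it (183 with the same sign, 6 with the other sign, from medians whose interval included 0, and 2 at 0) and 9 reversed, of 570 alternative ratios of named genes 295 stayed, 275 moved and 0 reversed, and all 6 alternative shares of the macrophage-like cluster stayed. The stricter cell filter (at least 1000 genes, at most 5% mitochondrial) removed 0 cells and gave no value. No paired analysis was possible because each group had 1 library. Unless said otherwise, the cause was not tested.

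Gene counts moved with the CPM minimum, which sets how many genes enter. At 20 and 100 CPM, genes at least 2-fold higher in WT IL-33 than in WT vehicle numbered 795 and 309, and lower genes 620 and 200. For cKO IL-33 against WT IL-33, 662 and 254 were higher, and 293 lower at 100 CPM. For cKO IL-33 against WT vehicle, 25 and 7 were higher and 11 were lower at 20 CPM, and 7 were lower with totals without mitochondrial and ribosomal genes.

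In WT IL-33 against WT vehicle, the NF-kB target median was 2.72 with a pseudocount of 10 CPM. The chemokine median was 5.12 in cells without other leukocyte markers (736 of 2202 and 648 of 2709 cells kept), 4.88 in male-called cells, 4.95 in cells with at most 5000 UMIs, 3.59 with a pseudocount of 10 CPM, 4.17 with no filter on low values and 4.99 for members at 50 CPM or more. The homeostatic median was -0.56 with TMM, -0.61 with totals without mitochondrial and ribosomal genes, -0.54 with equal weights, -0.57 in cells without other leukocyte markers, -0.55 in thinned cells, -0.64 in male-called cells and -0.62 in cells with at most 5000 UMIs.

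In cKO IL-33 against WT IL-33, the NF-kB target median was -3.12 in female-called cells, -3.55 in cells with at most 5000 UMIs, -2.78 with a pseudocount of 10 CPM and -3.52 for members at 50 CPM or more. The chemokine median was -5.04 in cells without other leukocyte markers, -5.03 in thinned cells, -4.56 in female-called cells, -4.69 in cells with at most 5000 UMIs, -3.58 with a pseudocount of 10 CPM, -4.01 with no filter and -5.03 for members at 50 CPM or more. The homeostatic median was 0.59 with TMM, 0.66 with totals without mitochondrial and ribosomal genes, 0.65 with equal weights, 0.71 in cells without other leukocyte markers, 0.68 in thinned cells, 0.54 in female-called cells, 0.66 without cells holding Xist and Y-linked UMIs and 0.74 in cells with at most 5000 UMIs.

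Medians that reversed were small in size or of few members. In WT IL-33 against WT vehicle they were the PI3K-Akt and mTOR list (0.15) and the sex-linked genes (2.67) for members at 50 CPM or more, MHC class I presentation with totals without mitochondrial and ribosomal genes (-0.0015) and in male-called cells (-0.0061), and proteases and cathepsins with no filter (0.092). In cKO IL-33 against WT IL-33 it was MHC class II presentation with no filter (0.10). In cKO IL-33 against WT vehicle they were type I interferon genes in cells without other leukocyte markers (0.090), MHC class II presentation in cells with at most 5000 UMIs (-0.060) and the sex-linked genes for members at 50 CPM or more (0.58). Of the response genes in cKO IL-33 against WT vehicle, those higher in WT IL-33 had medians of 0.10 and 0.095 at 1.5-fold and 3-fold, and those lower had -0.010 at 3-fold.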

Other observations

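Chosen only after the data were seen were the comparison of Xist and Y-linked cells within WT IL-33 and the list of other glucocorticoid-responsive genes, which was written once Fkbp5 and Ddit4 had been seen but before its own ratios were.

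Within the WT IL-33 library, inflammatory genes were higher in the 670 cells with Y-linked UMIs and no Xist (median 3780 UMIs) than in the 802 cells with Xist and no Y-linked UMI (median 3870.5 UMIs). Il12b was at 1884 CPM against 628 CPM, 2.999-fold higher (2.86 to 3.14), Ccl4 at 7432 CPM against 2909 CPM, 2.55-fold (2.498 to 2.61), Ccl3 2.71-fold (2.64 to 2.79), Il1b 2.41-fold (2.31 to 2.52) and Tnf 2.07-fold (1.91 to 2.24). P2ry12 was 1.63-fold higher (1.55 to 1.72) in the Xist cells. All 14 genes with the highest log2 ratios to vehicle at a pseudocount of 1 CPM, leaving out Xist, were higher in the Y-linked cells, by 1.297-fold to 2.999-fold. The cells were also spread differently over the deposited clusters. Cluster 1, which is led by inflammatory genes, held 87.2% (84.4 to 89.6%) of the Y-linked and 74.2% (71.0 to 77.2%) of the Xist cells, and cluster 0 held 3.73% and 10.2%, so part of each ratio goes with where the cells lay. Within cluster 1 alone (584 Y-linked and 595 Xist cells) the ratios were smaller, at 2.69-fold (2.56 to 2.83) for Il12b, 2.31-fold (2.25 to 2.36) for Ccl4, 2.46-fold (2.38 to 2.53) for Ccl3, 2.198-fold (2.10 to 2.30) for Il1b and 1.86-fold (1.71 to 2.02) for Tnf, with P2ry12 1.405-fold higher (1.317 to 1.4997) in the Xist cells.

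By list, the median log2 ratio of Xist over Y-linked cells was -0.45 for NF-kB targets (23 of 23 lower in Xist cells), -0.50 for chemokines (14 of 15) and 0.44 for homeostatic genes (19 of 20 higher). In cells with at most 5000 UMIs (574 Xist and 492 Y-linked cells) these were -0.58, -0.54 and 0.43. The cell sets were defined from the data, cells of each sex come from different animals, and the number of animals is not given in the sources used here, so a difference between sexes is not separated from a difference between animals.

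A pattern seen in cKO IL-33 against WT vehicle was that Fkbp5, Ddit4, Tsc22d3 and Sult1a1 were higher, with a median log2 ratio of 1.39 (0.28 in WT IL-33 against WT vehicle). The first 3 of these are textbook glucocorticoid targets. Fkbp5, Ddit4 and Sult1a1 were among the genes with the highest ratios in this comparison, so the median of 1.39 is high by choice. A difference between female and male cells is 1 candidate explanation: within WT IL-33 the same 4 genes had a median of 0.95 (0.78 to 1.14) in Xist over Y-linked cells, as this explanation requires. Those Xist cells also had lower inflammatory genes and lay less often in cluster 1 (74.2% against 87.2%). This median therefore cannot separate sex from the inflammatory state of the cells. Glucocorticoid exposure is another: 5 of 9 other responsive genes could be measured and had a median of 0.35, at the 99.6 percentile of matched random lists, with Sgk1 1.43-fold and Cebpd 1.28-fold higher. Neither test excludes the other explanation, and the floxed alleles, the injection and the animals also differ and were not tested.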
